A study of Mus musculus with 8 samples.

How the data were processed

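RNA of cardiomyocytes from WT and KO mice was sequenced at e13.5 and in adults, in 8 libraries that formed 4 groups of 2. The authors amplified 200 ng of total RNA per library with Smart-seq2 and made libraries with a SMARTer kit. The deposited table holds estimated counts (expected counts) per gene, per the labels made with RSEM on the mm10 genome. The values were read as counts not scaled between libraries, since they are whole numbers with differing totals, although the name of the table speaks of normalised input. The version of RSEM, the aligner and the annotation are not given in the sources used here. Total counts were 20395600 and 20202970 for WT e13.5, 16495084 and 18020211 for KO e13.5, 19760351 and 17159009 for WT adults, and 19716681 and 17884518 for KO adults. Of 51826 gene identifiers, 51633 had a symbol and position in GENCODE vM21, and the other 193, of which 32 were tested, took at most 0.0184% of the counts of a library. No library and no column was left out.

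Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, with Python 3.11.15, matplotlib 3.10.9 and BLAST 2.17.0 for sequences and plots. Genes were kept by filterByExpr (16623 genes), and library sizes were scaled by TMM, with factors from 0.770 to 1.44. A quasi-likelihood negative binomial model with 4 group means and no replicate term was fitted to all 8 libraries, with 4 residual degrees of freedom, a prior of 5.74 degrees of freedom, a common dispersion of 0.212 and a median biological coefficient of variation of 0.428. The contrasts were KO against WT at e13.5, in adults and averaged over both ages, adult against e13.5 in each genotype, and the interaction of genotype and age. Tests were two-sided, and a gene counted as changed at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. CPM values were computed with the TMM-scaled library sizes. A fold against a group with 0 counts was computed against a floor of 3 counts over the group, and fitted ratios against 1 to 3 counts, which the model moderates, were given with a 95% counting interval of the ratio of the counts. Log2 CPM for correlations between libraries used a prior count of 2.

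Gene lists were tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry, each adjusted over the 32 lists with at least 5 tested members. The lists on heart function were sarcomere and Z-disc, fetal cardiac genes, calcium handling and ion channels, cardiac transcription factors, hypertrophy and load response, atrial, ventricular and conduction system markers. Those on metabolism and cell state were fatty acid oxidation, oxidative phosphorylation, glycolysis, cell cycle, extracellular matrix, integrated stress response and one-carbon genes, p53 and apoptosis, interferon response, imprinted genes, cytoplasmic ribosomal proteins, mitochondrially encoded genes, immediate early and heat shock genes, circadian clock and sex-linked genes. Those on other cell types were fibroblast, endothelial, smooth muscle and pericyte, epicardial, macrophage and leukocyte, erythroid, neural crest, neuron and Schwann cell, skeletal muscle, adipocyte, and liver and lung markers. The lists, the model, the comparisons and the rule for naming genes were fixed before the data were examined.

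Named genes were LncSync if listed and Sync, then per comparison the 8 genes with the largest rise and the 8 with the largest fall among changed genes whose libraries did not overlap between the groups and whose higher group had a mean of at least 5 CPM, passing over genes without a proper name. Where fewer genes passed, the genes of smallest p were named and said to miss the threshold. From each list up to 4 changed members by smallest p, or 2 members of highest level where none changed, were added, with the sex-linked genes in every library. Genes outside this rule are said to be chosen after their values were seen, and where few genes changed, those without a proper name were also given.

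Near-identical copies were searched by aligning the transcripts of the called genes to all transcripts of the reference with BLAST, taking hits in another gene of at least 95% identity over at least 50% of the transcript. Each called gene was set against 20 tested genes of like level. Other splits of the 8 libraries into 2 equal groups were fitted with additive terms for age and split. The alternatives were no filter, a filter of at least 5 CPM in at least 2 libraries, median-of-ratios and upper quartile scaling, robust quasi-likelihood, the DESeq2 Wald test, only the 4 libraries of a comparison, the replicate number as a block, each library left out in turn, an added fold change threshold of 1 on the log2 scale, and for lists an estimated correlation and fry. Pseudocount alternatives had been planned for values that are no counts and did not apply. Alternatives added after the data were seen were the replicate number as a block at e13.5 alone, leaving out ribosomal RNA, mitochondrial and haemoglobin genes, and an additive model.

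The procedure was tested on simulated data. In the comparison of KO with WT at e13.5, run on 16155 simulated genes, it called 0 of 67 genes with a 2-fold change, 2 of 66 with a 4-fold change and 26 of 63 with an 8-fold change. In the adult comparison, run on 16078 genes, the numbers were 0 of 62, 4 of 66 and 28 of 65, and for adult against e13.5 in WT, run on 14244 genes, 0 of 57, 0 of 57 and 11 of 57. Genes simulated without a change gave 2, 3 and 1 calls in the 3 comparisons. For adult against e13.5 all libraries were simulated at adult levels with few changed genes, unlike the real comparison.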

Results

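The series compared cardiomyocytes from the hearts of wild-type (WT) mice with those of mice homozygous for a null allele of LncSync (KO), a long noncoding RNA. Cells were taken from embryos at e13.5 (days after conception) and from adults, so there were 4 groups, each with 2 libraries. All 8 libraries carried the same strain label, C57BL/6. Each library was made from 200 ng of total RNA amplified with Smart-seq2. Total counts ran from 16495084 in KO e13.5 replicate 1 to 20395600 in WT e13.5 replicate 1. A floor of 3 counts in a single library corresponded to 0.103 to 0.207 CPM, the counts scaled to an equal total per library, while folds given as "at least" were set against 3 counts over both libraries of a group. Values after ± are the standard error of a log2 fold change or the standard deviation (SD, n = 2) of a CPM, and counting intervals and floors cover counting error alone. Fitted ratios are moderated by the model at low counts, so they differ from the ratio of the counts, to which the counting intervals belong. The labels did not state whether the 2 libraries of a group came from separate animals, so the p-values measure the spread between these samples. The p-values are two-sided and, unless stated otherwise, come from edgeR, adjusted by the Benjamini-Hochberg method over 16623 genes.

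Genes of the mitochondrial genome took 3.21% to 4.36% of the counts at e13.5 and 22.6% to 28.8% in adults. Haemoglobin genes took 4.65% and 2.89% of the counts in the WT e13.5 libraries and 15.5% and 3.19% in the KO e13.5 libraries, but at most 0.0136% in adults. Ribosomal RNA took 12.3% and 7.80% in WT and 6.97% and 13.6% in KO at e13.5, and 0.688% to 0.828% in adults. Across genes, which are not independent replicates, the log2 CPM of the 2 WT e13.5 libraries correlated with r = 0.913 and those of the 2 KO e13.5 libraries with r = 0.918. Library 1 of WT and library 1 of KO at e13.5 correlated more closely, with r = 0.960, as did library 2 of each genotype, with r = 0.954. In adults the libraries of a group correlated with r = 0.978 in WT and 0.957 in KO. Counts for the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were present in all 8 libraries. Xist, the RNA that coats the inactive X chromosome of female cells, lay at 47.3 ± 48.8 CPM in WT and 31.7 ± 5.24 CPM in KO at e13.5, but at 0.103 and 0.232 CPM in adults. By these genes the e13.5 libraries held cells of both sexes and the adult libraries few if any female cells, so sex went with age. The liver gene Alb was at 0 CPM in library 1 of both adult genotypes and at 38.8 and 56.2 CPM in library 2 of WT and KO.

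LncSync itself could not be measured by name, because none of the 51826 genes in the count table or in the reference annotation carries that name. The loss of its transcript in the KO libraries was therefore not checked. Whether one of the noncoding transcripts absent from KO is LncSync under another identifier was not checked either. Sync, which encodes the intermediate filament protein syncoilin, is given here with no claim of a link (ENSMUSG00000001333, chromosome 4, 129287617 to 129308559). Its level was 1.49 ± 0.0855 CPM in WT and 1.82 ± 1.68 CPM in KO at e13.5, with a log2 fold change of 0.31 ± 0.65 (adjusted p = 1). In adults it was 16.7 ± 2.03 CPM in WT and 18.9 ± 3.58 CPM in KO (log2 0.17 ± 0.62, adjusted p = 1). Sync rose with age in both genotypes, by 3.48 ± 0.69 in WT (adjusted p = 0.00435) and 3.35 ± 0.69 in KO (adjusted p = 0.00473).

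At e13.5, the comparison of KO with WT asked which transcripts differ in the embryonic heart without LncSync. Mocs1, which encodes an enzyme of molybdenum cofactor synthesis, fell from 11.4 ± 0.364 CPM to 0.567 ± 0.0941 CPM (ENSMUSG00000064120, chromosome 17, 49428362 to 49455435; log2 -4.31 ± 0.50, adjusted p = 0.0186). C430049B03Rik, a noncoding transcript from the X chromosome, was at 18.98 ± 0.539 CPM in WT and at 0 in both KO libraries, at least 260.3-fold lower (adjusted p = 0.0116). The other 10 of the 12 changed genes were higher in KO, and 9 of these are annotated as pseudogenes, against 413 pseudogenes among all genes tested. All 10 share near-identical sequence with another gene, which makes their counts uncertain. Rpl3-ps1, a copy of a ribosomal protein gene, rose from 0.616 ± 0.237 to 672 ± 28.1 CPM (chromosome X, 13202571 to 13203780; log2 10.09 ± 0.77, adjusted p = 0.00376). Tpm3-rs7, a copy of a tropomyosin gene, rose from 1.11 ± 0.0599 to 306 ± 54.5 CPM (chromosome 14, 113314608 to 113316754; log2 8.10 ± 0.64, adjusted p = 0.00376). Rps3a2 had 2 counts in WT against 121 ± 16.7 CPM in KO, a fitted ratio of 2626 with a counting interval of 867 to 25894 (adjusted p = 0.00256). Rpl15-ps2 (fitted ratio 585 with a counting interval of 194 to 5798), Rpl34-ps1 (fitted ratio 338 with a counting interval of 132 to 1885) and the serpin pseudogene Serpina3h (fitted ratio 109 with a counting interval of 36.9 to 532) also rose. Gm10020, a pseudogene of Rpl15, was at 0 in WT and 87.6 ± 6.82 CPM in KO, at least 1501-fold higher. The remaining 3, Gm17383, Gm6682 and Gm3756, are pseudogenes of an alpha-tubulin gene and reached 18.1, 13.97 and 18.3 CPM in KO.

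Several named genes missed the threshold in the embryonic comparison. The glycosyltransferase gene B3gnt3 had a log2 fold change of -4.08 ± 0.62 (adjusted p = 0.0795), and Wdfy1, an endosomal adaptor gene, one of 2.90 ± 0.45 (adjusted p = 0.0822). Rpl3 had -2.27 ± 0.48 (adjusted p = 0.519), and the next values were -2.55 ± 0.58 for Plac9b, -2.03 ± 0.48 for Tob2, 2.49 ± 0.59 for Plac1 and -1.94 ± 0.55 for Efnb3, all with larger p. The potassium channel gene Kcnj3 had -1.82 ± 0.47 and the cytokine gene Il15 -2.04 ± 0.55. The log2 fold change was 0.16 ± 0.66 for the sarcomeric actin Actc1, -0.24 ± 0.52 for the calcium pump Atp2a2, 0.48 ± 0.55 for its regulator Pln and 0.13 ± 0.56 for the ventricular myosin light chain Myl2. The alpha myosin heavy chain Myh6 had -1.27 ± 0.57 (adjusted p = 1) and the atrial peptide gene Nppa -0.23 ± 0.94. The sarcomere and Z-disc list, to which some of these belong, had 20 of 25 fold changes negative (median -0.35, adjusted p = 0.111). Among haemoglobin genes, whose share was largest in KO e13.5 replicate 1, Hba-a1 had 2.08 ± 1.15.

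Among the 32 gene lists, calcium handling and ion channels lay lower in KO at e13.5, with a median log2 fold change of -0.39 over 29 genes (adjusted p = 0.00973, and 0.487 with an estimated correlation). Skeletal muscle markers lay lower with a median of -0.25 (adjusted p = 0.0111, and adjusted p = 0.794 with an estimated correlation), of which Myl1 had -2.80 ± 0.84, with 834 and 129 CPM in the WT libraries and 105 and 34.1 CPM in KO. Cell cycle genes lay higher with a median of 0.28 over 40 genes (adjusted p = 0.0107, and adjusted p = 0.794 with an estimated correlation). Adipocyte markers lay higher with a median of 0.95 over 5 genes (adjusted p = 0.0107, and adjusted p = 0.487 with an estimated correlation). KO replicate 2 alone stood far above, with adipocyte levels of -0.87 and -1.67 in WT and -0.61 and 1.03 in KO (log2, centred over all libraries). With no filter on low counts the skeletal muscle and adipocyte lists did not pass (adjusted p = 0.179 and 0.810), and with a stricter filter on low counts the skeletal muscle list did not pass (adjusted p = 0.405) and the adipocyte list was too small to test. In none of these 4 lists did a single gene pass over all genes, and adjusted over the list alone 0 rose and 2 fell in the calcium list, with 0 in the other 3. In the atrial and the ribosomal protein lists, which did not pass as lists, 1 and 1 gene fell adjusted over the list alone. The erythroid list, whose share differed between libraries, had a median of 1.04 (adjusted p = 0.0574). With fry, 0 of the 32 lists passed at e13.5, the smallest adjusted p being 0.518. In place of 4 lists, 8 passed with the stricter filter, 10 with the replicate number as a block at e13.5 alone and 11 with DESeq2.

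The 12 genes at e13.5 (398 at an unadjusted p under 0.05) became 5, all among the 12, when the 4 e13.5 libraries were fitted alone, 10 higher and 25 lower without WT e13.5 replicate 1, 16 higher and 14 lower with DESeq2 and 32 higher and 55 lower without a filter, in place of 10 and 2. Of the 4 lists, 2 passed without KO e13.5 replicate 1 (9 lists in all, all lower) and 2 without WT e13.5 replicate 2 (10 in all, all lower), 1 without KO e13.5 replicate 2 (7 in all) and 1 without WT e13.5 replicate 1 (6 in all), and on simulated data 26 of 63 genes with an 8-fold change were found against 2 of 66 with a 4-fold change.

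In adults, the same comparison asked which transcripts differ in the mature heart. Gvin1, an interferon-inducible GTPase gene, was at 45.4 ± 25.7 CPM in WT and at 0 in both KO libraries, at least 473-fold lower (ENSMUSG00000045868, chromosome 7, 106156556 to 106215326; adjusted p = 0.0323). The other 7 of the 8 changed genes were higher in KO, and 5 of them, like Gvin1, share near-identical sequence with another gene. Rpl3-ps1 was at 0 in WT and 110.2 ± 61.0 CPM in KO, at least 1166-fold higher (adjusted p = 0.00461). Rps3a2 was at least 374-fold higher, Tpm3-rs7 at least 323-fold and Gm10020 at least 465-fold. Rpl34-ps1 had 1 count in WT against 28.9 ± 13.9 CPM in KO, a fitted ratio of 764 with a counting interval of 164 to 36238. All 5 of these had also risen at e13.5, out of the 15 genes that changed at either age. Mindy4b-ps rose from 0.201 ± 0.202 to 14.04 ± 0.174 CPM (log2 6.13 ± 0.81, adjusted p = 0.0480), and 6330403K07Rik from 1 count to 4.79 ± 1.80 CPM (fitted ratio 125 with a counting interval of 26.8 to 6039). With the replicate number as a block at e13.5 alone, 22 genes changed in adults, 10 higher and 12 lower.

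Below the threshold in adults, Pttg1, the gene of the chromosome segregation protein securin, had a log2 fold change of -4.89 ± 0.68 (adjusted p = 0.0597), from 52.3 ± 6.64 CPM in WT to 1.75 ± 0.507 CPM in KO. Pagr1a had 4.47 ± 0.64 (adjusted p = 0.0602) and Trim12a -5.20 ± 0.80 (adjusted p = 0.0924). Lrat, which encodes the enzyme that esterifies retinol, went from 7.56 ± 0.807 CPM in WT to 1 count in KO (adjusted p = 0.0602). Values for further genes were -3.89 ± 0.66 for Tmem100, -4.27 ± 0.76 for Angptl7, -3.27 ± 0.58 for Arrdc2, -2.25 ± 0.40 for the amino acid transporter Slc38a1 and -2.95 ± 0.57 for Il15. Among heart muscle genes, the values were -0.44 ± 0.56 for Myh6, 0.03 ± 0.66 for Actc1, -0.12 ± 0.52 for Atp2a2, -0.29 ± 0.55 for Pln and 0.44 ± 0.59 for the fatty acid binding protein Fabp3. The peptide gene Nppa, a marker of cardiac load, lay at 30.7 ± 4.13 CPM in WT and 30.7 ± 18.3 CPM in KO.

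Extracellular matrix genes lay higher in adult KO libraries, with 24 of 26 fold changes positive and a median of 0.74 (adjusted p = 3.04e-04, and adjusted p = 0.814 with an estimated correlation). In this list Sparc had 0.62 ± 0.55 and Eln, the gene of elastin, 1.05 ± 0.75. Fibroblast markers had 15 of 15 fold changes positive (median 0.33, adjusted p = 0.0626) and endothelial markers 14 of 17 (median 0.33, adjusted p = 0.0663), and neither list passed. The genotypes overlapped between libraries. Fibroblast levels were 0.786 and -0.168 in WT and 0.779 and 0.451 in KO, and endothelial levels 0.616 and 0.395 in WT and 0.937 and 0.21 in KO (log2, centred over all libraries). Macrophage and leukocyte markers lay higher with a median of 0.51 (0.49 with genes at 0 in a group set to their bound) (adjusted p = 0.00373, and adjusted p = 0.683 with an estimated correlation), and Lyz2 among them had 0.92 ± 0.63. Immediate early and heat shock genes lay lower with a median of -0.68 (adjusted p = 7.26e-06, and adjusted p = 0.683 with an estimated correlation). In that list the chaperone gene Hspa1a stood at 105 ± 119 CPM in WT and 18.97 ± 17.3 CPM in KO, and WT library 1 alone had 189.8 CPM. Epicardial markers lay lower with a median of -0.74 (adjusted p = 3.04e-04, and adjusted p = 0.683 with an estimated correlation), with -0.79 ± 0.71 for the uroplakin gene Upk3b. Circadian clock genes lay lower with a median of -0.64 (adjusted p = 0.0131, and adjusted p = 0.683 with an estimated correlation), and adjusted over the list alone 2 of 16 rose and 4 fell, against 0 over all genes. Nr1d1 had 1.80 ± 0.51 and Tef -1.11 ± 0.57, both genes of clock transcription factors. Conduction system markers lay lower with a median of -0.37 (adjusted p = 0.0368, and adjusted p = 0.683 with an estimated correlation).

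Cytoplasmic ribosomal protein genes had a median of 0.39 in adult KO against WT (adjusted p = 0.0131, and adjusted p = 0.875 with an estimated correlation), mitochondrially encoded genes one of 0.22 (adjusted p = 0.0192, and adjusted p = 0.796 with an estimated correlation). The ribosomal protein list lay at -0.739 and -1.081 in WT and -0.149 and -1.076 in KO replicates 1 and 2 (log2, centred over all libraries). KO replicate 1 alone thus stood higher. The nuclear oxidative phosphorylation genes had a median of 0.24, with 37 of 40 positive (adjusted p = 0.0301, and adjusted p = 0.875 with an estimated correlation). Their levels were 0.458 and 0.293 in WT and 0.732 and 0.373 in KO replicates 1 and 2. KO replicate 2 thus lay between the WT libraries, and KO replicate 1 alone stood above both. In these 9 lists no gene passed over all genes, and adjusted over the list alone 1 ribosomal protein gene fell besides the clock genes. The neural crest, neuron and Schwann cell list had 1 such gene, though the list did not pass (adjusted p = 0.202). With fry, 0 of the 32 lists passed in adults for a common direction (smallest adjusted p 0.933), and the clock and neural lists passed for a change in either direction (adjusted p = 0.0446 for each).

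The 8 adult genes (377 at an unadjusted p under 0.05; 23 higher and 31 lower with DESeq2; 29 higher and 35 lower without a filter) became 0 without WT adult replicate 1, and 4 without KO adult replicate 1 or without WT adult replicate 2, and a fit of the 4 adult libraries alone called 2 genes, none of them among the 8. Scaling by the median of ratios gave 10 higher and 3 lower and upper quartile scaling 9 higher and 3 lower, in place of 7 and 1, and of the 9 lists 2 passed without KO adult replicate 1, 3 without WT adult replicate 2, 6 without KO adult replicate 2 and 7 without WT adult replicate 1.

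Averaged over both ages, 13 genes rose and 7 fell in KO (20 in all; 470 at an unadjusted p under 0.05). With the replicate number as a block at e13.5 alone, 16 rose and 17 fell. There were 28 higher and 31 lower with DESeq2, 46 and 54 without a filter, 10 and 1 without KO adult replicate 1, and 17 and 18 without WT e13.5 replicate 1. Beyond those named above, Wdfy1 rose (log2 2.26 ± 0.31, adjusted p = 0.0296) with 4.98 ± 0.792 and 37.4 ± 0.808 CPM at e13.5 and 8.47 ± 2.34 and 25.9 ± 2.49 CPM in adults for WT and KO (ENSMUSG00000073643, chromosome 1, 79702262 to 79776143). Trim12a, a member of the Trim family of antiviral genes, fell (log2 -4.02 ± 0.53, adjusted p = 0.0200; ENSMUSG00000066258, chromosome 7, 104299894 to 104315466). Rpl3, a gene of the large ribosomal subunit, fell with a log2 fold change of -2.33 ± 0.34 (adjusted p = 0.0457) and was the 1 ribosomal protein gene of 40 to pass, both over all genes and adjusted over the list alone. Gm16867, 2610507I01Rik and Gm15446 fell, and Mrpl48-ps, a pseudogene of a mitochondrial ribosomal protein gene, rose. Of the 32 lists, 8 passed with the preset correlation and 0 with an estimated one. Adipocyte (median 0.82, adjusted p = 0.00844) and leukocyte markers (median 0.66, adjusted p = 0.00106) lay higher. In adults the adipocyte levels were -1.23 and 1.03 in WT and 0.561 and 0.978 in KO, so WT replicate 1 alone stood lower. Calcium handling genes (-0.23, adjusted p = 0.00731), immediate early and heat shock genes (-0.36, adjusted p = 0.00106), clock genes (-0.57, adjusted p = 0.00844), and epicardial (-0.63, adjusted p = 0.00106), conduction (-0.47, adjusted p = 0.0145) and atrial markers (-0.55, adjusted p = 0.0211) lay lower. With an estimated correlation their adjusted p values ran from 0.551 to 0.776.

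**Figure D1:**
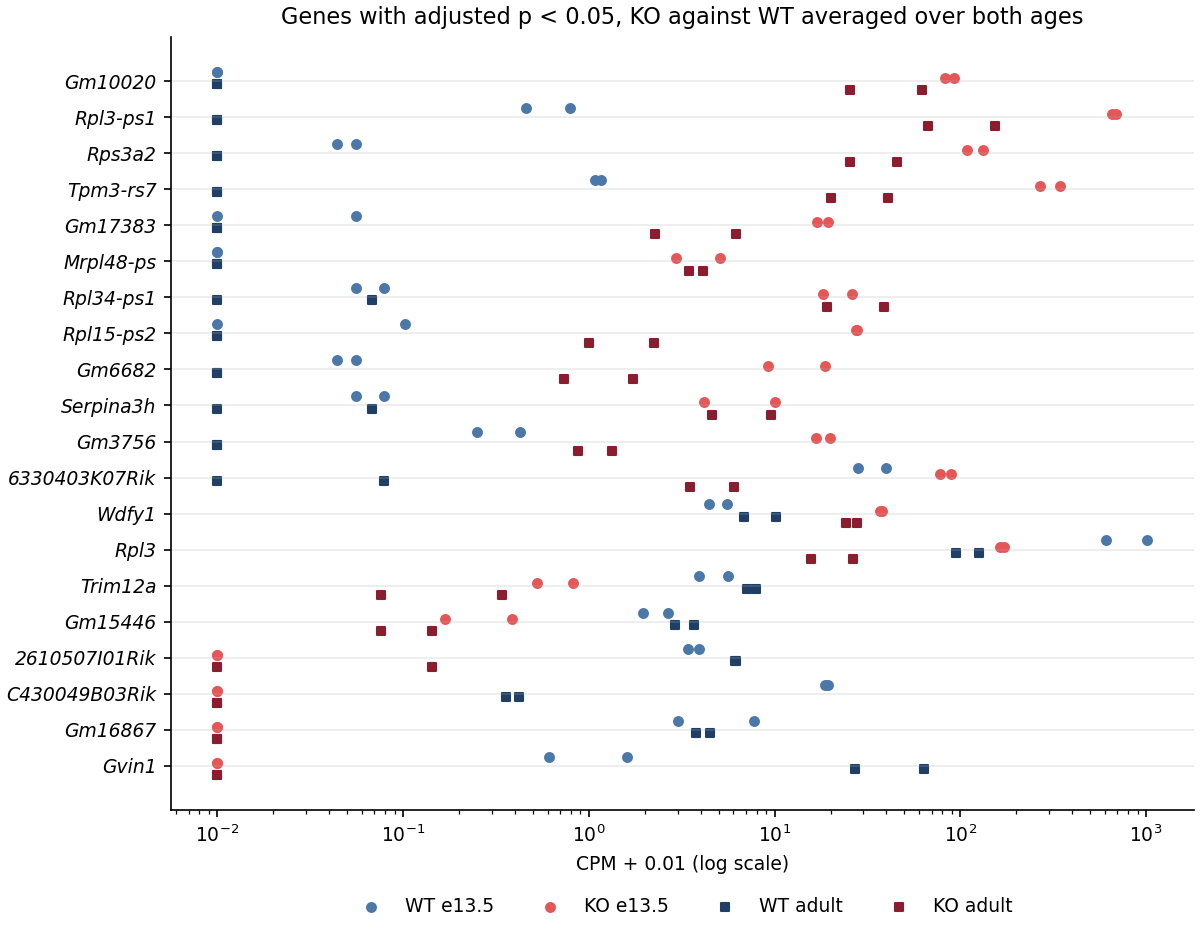
Level of the 20 genes that differed between KO and WT averaged over both ages, one point per library; the axis gives CPM plus 0.01 on a log scale, circles e13.5, squares adult, blue WT and red KO. Points at the left edge are libraries with 0 counts, as for Gm10020 in all 4 WT libraries and Gvin1 in all 4 KO libraries.

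Of the 20 genes, 15 have a near-identical transcript of another gene in the annotation, so their counts are uncertain, because reads can be assigned to either copy. For Rpl3 and Tpm3 the parent gene fell as its copy rose. At e13.5, Rpl3 went from 813 CPM in WT to 168 CPM in KO while Rpl3-ps1, 99.8% identical to it, went from 0.616 to 672, and the sum of both went from 813 to 840.1. In adults the sum went from 110.2 to 131 CPM. Tpm3, chosen after its values were seen as the parent gene of Tpm3-rs7, went from 321 to 118 CPM at e13.5, and the sum of both from 322 to 425 CPM. The sum for Rps3a2 and its parent Rps3a1 had a log2 ratio of -0.15 at e13.5 and 0.21 in adults. Rps3a1 makes up most of this sum, which therefore changes little whether or not reads moved. Rps3a1 went from 683 to 494 CPM at e13.5, but in adults it did not fall, with 288 CPM in WT and 299 CPM in KO. Rpl15, the copy added for Gm10020, did not fall either, with 403 and 421 CPM at e13.5 and 55.1 and 91.1 CPM in adults for WT and KO. With the copy of highest level added, the log2 ratio of KO to WT at e13.5 and in adults was 4.58 and 4.94 for Serpina3h, -3.64 and -2.20 for Gm16867 and -1.28 and -1.55 for Gm15446, and in adults -1.31 for Gvin1 and 1.29 for Gm10020. Mocs1, Wdfy1, Trim12a, C430049B03Rik, 2610507I01Rik, 6330403K07Rik and Mindy4b-ps, each changed in at least 1 comparison, had no such copy.

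**Figure D2:**
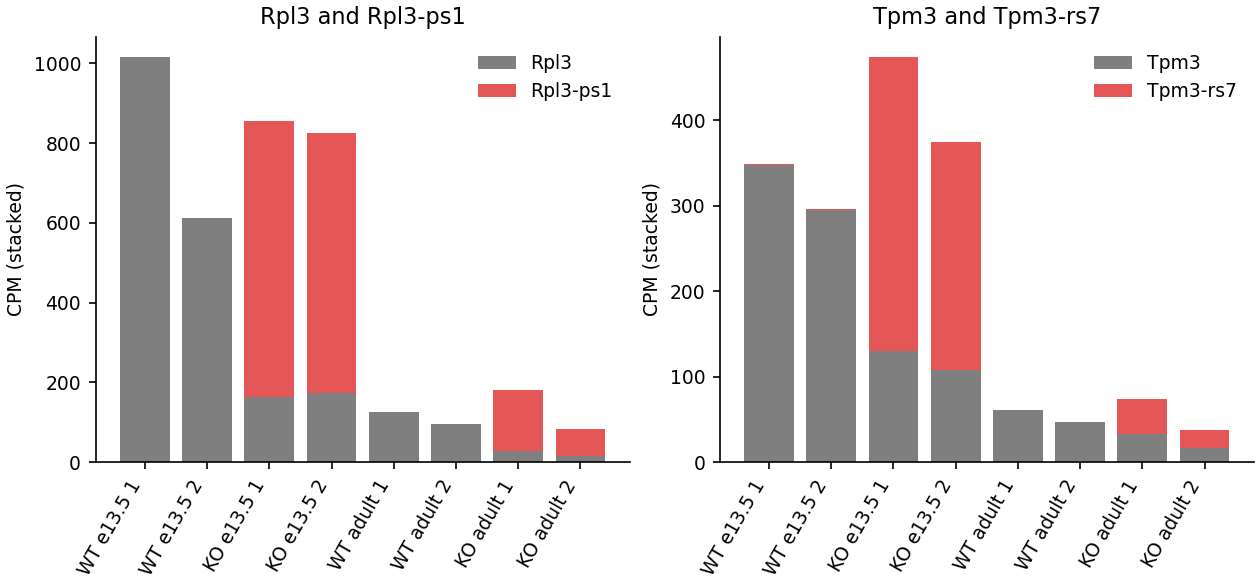
Stacked CPM of 2 parent genes and their near-identical copies, Rpl3 with Rpl3-ps1 and Tpm3 with Tpm3-rs7, one bar per library. In all 4 WT libraries nearly all counts fall on the parent gene, and in all 4 KO libraries the copy takes the larger part, with Rpl3-ps1 at 672 CPM and Rpl3 at 168 CPM on average at e13.5.

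The fold changes between KO and WT at e13.5 and in adults, which share no library, correlated across the 16623 genes with Pearson r = 0.220 and Spearman rho = 0.139. With 1 library left out r was between 0.105 and 0.169 (0.105 without WT e13.5 replicate 2, 0.124 without KO e13.5 replicate 1 and 0.133 without KO adult replicate 1), and it was 0.0676 without a filter and 0.325 with a stricter one. Without the 15 genes changed at either age, r was 0.155. Both fold changes also fell with transcript length (Spearman rho -0.264 at e13.5 and -0.171 in adults), and how far length contributes to r was not tested. Of those 15, 14 had the same sign at both ages, all but Mocs1, which was at 16.52 ± 1.744 CPM in adult WT and 18.1 ± 2.68 CPM in adult KO. The 5 genes higher at both ages compare with 0.00421 expected for independent lists of these sizes. Genes that moved at 1 age were tested for a difference between the ages by the interaction, given last.

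Adult and e13.5 libraries were compared within each genotype to show which genes differ between the ages. The share of other cells may differ too, as haemoglobin genes took 2.89% to 15.5% of the counts at e13.5 and at most 0.0136% in adults. A change with age thus need not lie within cardiomyocytes. The share of female cells, judged by Xist, also differed between the ages and cannot be told apart from age. In WT the calcium pump gene Atp2a2 rose from 120.4 ± 26.3 to 19418 ± 462 CPM (ENSMUSG00000029467, chromosome 5, 122453513 to 122502225; log2 7.33 ± 0.68, adjusted p = 2.42e-04), and the adult myosin heavy chain Myh6 rose by 4.13 ± 0.64 (adjusted p = 0.00130) to 42337 ± 595 CPM. The slow skeletal troponin gene Tnni1, expressed in fetal hearts, fell from 2097 ± 1034 to 0.162 ± 0.0638 CPM (log2 -13.63 ± 1.01, adjusted p = 1.69e-04). The fetal beta myosin heavy chain Myh7 fell with a log2 fold change of -5.69 ± 1.03. Among the embryonic globin genes, Hbb-y was at 8918 ± 5763 CPM in the embryo and at 0 in the adult, at least 87991-fold lower. In all, 2954 genes rose and 3509 fell in WT, each by at least 2-fold, and 3402 rose and 3481 fell in KO. Rises outnumbered falls with an adult library left out, by 1734 to 1256 without WT adult replicate 1 and 1844 to 1157 without WT adult replicate 2, and in KO by 2411 to 1770 without KO adult replicate 1 and 2264 to 1446 without KO adult replicate 2. On simulated data 11 of 57 genes with an 8-fold change were found. There 14053 of 14244 genes had no change and all libraries had adult levels, so this share does not measure the power of the real comparison. Genes that missed the threshold can still have changed.

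Among the large rises in WT were those of Cebpb, a transcription factor gene (at least 1668-fold, adjusted p = 2.13e-04), Fbp2, a muscle gluconeogenesis enzyme (at least 412-fold), Clec3b (at least 391-fold) and the potassium channel gene Kcnv2 (at least 292-fold). The kinase gene Mylk4 rose by 11.19 ± 0.73 to 377 ± 51.0 CPM. The ribosomal protein pseudogenes Rps6-ps4, Rpl10-ps1 and Rpl17-ps10 rose at least 1506-fold, 551-fold and 213-fold. Among the large falls were those of Hba-x (at least 12054-fold), Hbb-bh1 (at least 884-fold), the cartilage collagen Col2a1 (at least 354-fold) and Rps12l1 (at least 462-fold). The histone gene Hist1h2ap fell from 501 ± 293 CPM to 3 counts, and the atrial light chain Myl7 with a log2 fold change of -11.83 ± 1.48. Globin, histone and ribosomal protein genes have close relatives in the genome, and sharing of reads was not tested for them here.

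Of 29 calcium handling and ion channel genes, 20 rose and 1 fell in WT (23 and 1 adjusted over the list alone), with a median log2 fold change of 3.23 (adjusted p = 6.53e-09, and adjusted p = 0.0863 with an estimated correlation). In KO 22 rose and 1 fell (23 and 1 adjusted over the list alone), with a median of 2.99 (adjusted p = 4.39e-09, and adjusted p = 0.0831 with an estimated correlation). Kcnip2, a subunit of the transient outward potassium channel, rose by 8.53 ± 0.58 in WT and 9.18 ± 0.61 in KO, and Jph2, which links the T-tubule to the sarcoplasmic reticulum, by 5.52 ± 0.50 and 6.16 ± 0.52. Of 25 sarcomere and Z-disc genes 8 rose in WT and 12 in KO (8 and 12 adjusted over the list alone). Their medians were 1.16 and 1.56, with adjusted p = 9.80e-05 and 5.49e-05 (adjusted p = 0.410 and 0.409 with an estimated correlation). Myom2, a protein of the M-band, rose by 6.80 ± 0.70 in WT and Tcap by 3.79 ± 0.73. Ventricular markers had medians of 1.13 and 1.39 (adjusted p = 0.0753 and 0.0932), 4 of 10 rising and 2 falling in each genotype, while adjusted over the list alone 4 rose and 2 fell in WT and 5 and 3 in KO.

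All 30 fatty acid oxidation genes had positive fold changes in both genotypes, of which 21 passed in WT and 24 in KO (23 and 26 adjusted over the list alone). Their medians were 2.40 and 2.51, with adjusted p = 4.14e-09 and 3.39e-09 (adjusted p = 0.410 and 0.409 with an estimated correlation). Mlycd, malonyl-CoA decarboxylase, rose by 6.81 ± 0.53 in WT, Acsl1, which activates fatty acids, by 5.31 ± 0.62, and Esrra, a regulator of these genes, by 4.65 ± 0.53. Of 13 mitochondrially encoded genes 12 rose in WT and 13 in KO, the same numbers adjusted over the list alone, with medians of 4.42 and 4.87 and adjusted p = 5.13e-09 and 4.08e-09 (adjusted p = 0.308 and 0.335 with an estimated correlation). mt-Nd2 rose by 6.40 ± 0.64 and mt-Co3 by 5.72 ± 0.76 in WT. The nuclear oxidative phosphorylation genes had lower medians of 0.73 and 0.82 and adjusted p = 0.00597 and 8.48e-04 (adjusted p = 0.665 and 0.637 with an estimated correlation). Of 40 such genes, 4 rose in WT and 5 in KO (1 and 3 adjusted over the list alone), led by the muscle subunits Cox8b (2.79 ± 0.59 in WT), Cox7a1 (2.72 ± 0.68) and Cox6a2 (1.72 ± 0.60). In glycolysis 3 of 20 rose and 7 fell in WT, 2 and 9 in KO (3 and 8 in WT and 2 and 9 in KO adjusted over the list alone), with adjusted p = 0.0675 in WT and 0.0337 in KO for the list (adjusted p = 0.602 with an estimated correlation in KO). The lactate exporter Slc16a3 fell with a log2 fold change of -6.45 ± 0.53 in WT and the glucose transporter Slc2a1 with -4.32 ± 0.57.

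**Figure D3:**
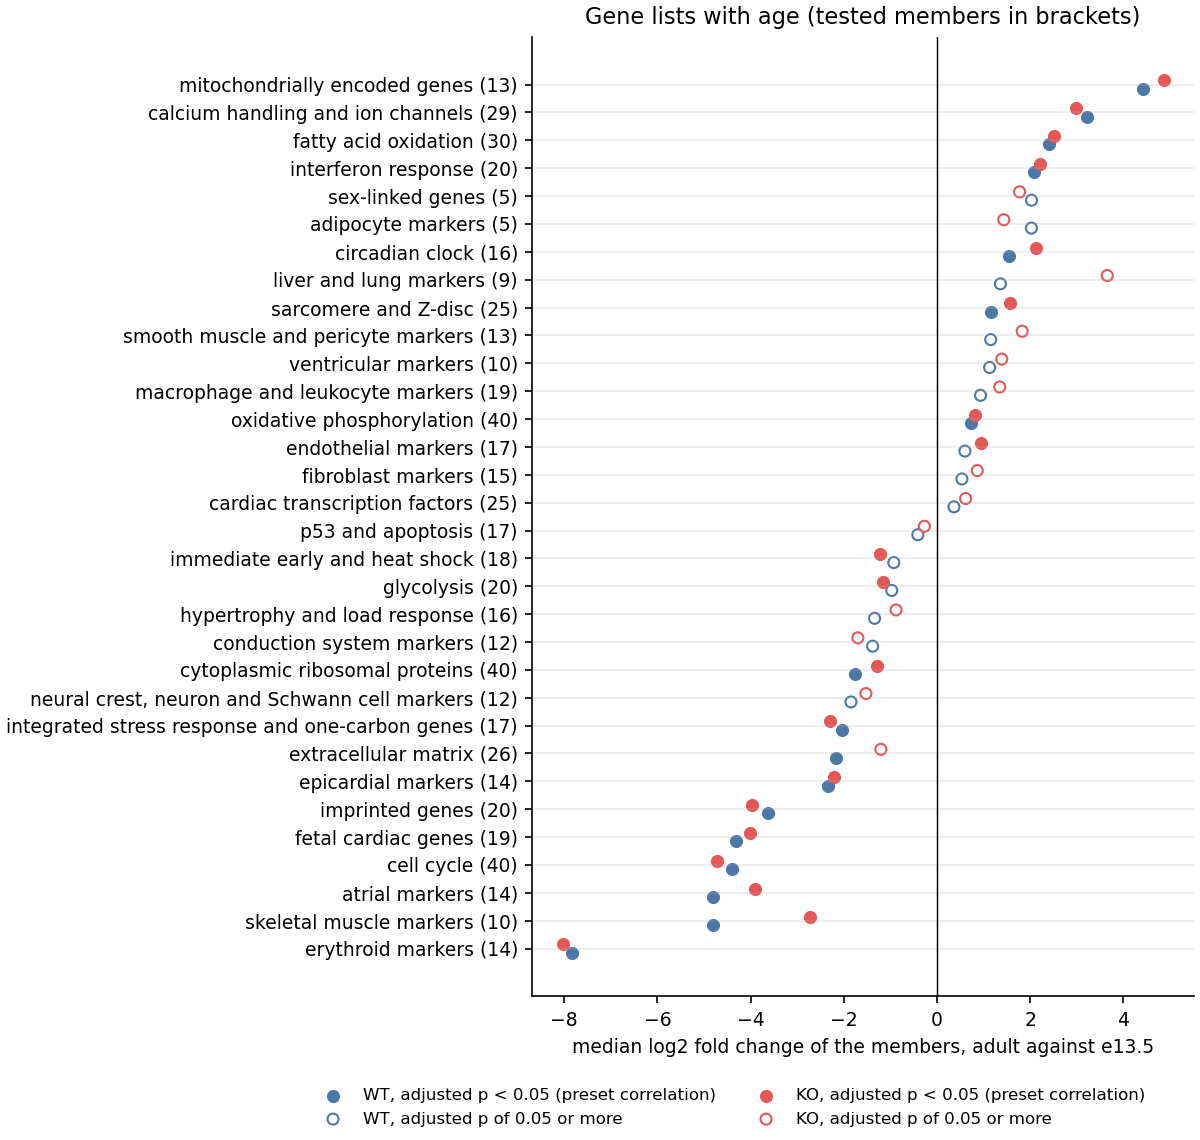
Median log2 fold change of each of the 32 gene lists, adult against e13.5, with WT in blue and KO in red; filled points have an adjusted p under 0.05 with the preset correlation, and genes at 0 in a group are set to their bound. The mitochondrially encoded genes lie highest, at 4.42 in WT, and the erythroid markers lowest in both genotypes.

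Proliferation and fetal genes fell. Of 40 cell cycle genes 37 fell in WT and 38 in KO (38 and 38 adjusted over the list alone). Their medians were -4.39 and -4.72, with adjusted p = 7.06e-15 and 2.75e-16 (adjusted p = 0.308 and 0.335 with an estimated correlation). The mitotic kinase genes Plk1 and Aurkb fell with log2 fold changes of -7.09 ± 0.70 and -5.54 ± 0.54 in WT. Of 19 fetal cardiac genes 1 rose and 12 fell in WT, and 1 and 11 in KO (1 and 13 in WT, 1 and 12 in KO adjusted over the list alone), with adjusted p = 5.76e-05 and 8.48e-04 (adjusted p = 0.308 and 0.409 with an estimated correlation) and medians of -4.32 and -4.02. The RNA-binding protein gene Igf2bp3 fell with -8.64 ± 0.62 and the light chain Myl4 with -11.05 ± 1.01 in WT. Of the 19 fetal cardiac genes 14 also belong to another list, such as Myl4, Myl7, Nppa, Sln and Bmp10 to the atrial markers. The falls of the fetal and the atrial list are therefore not separate results. Whether the share of atrial cells differed between the ages was not tested. Of 20 imprinted genes 14 fell in WT and 13 in KO (17 and 13 adjusted over the list alone), with adjusted p = 1.47e-05 and 6.30e-05 and medians of -3.63 and -3.97 (adjusted p = 0.308 and 0.335 with an estimated correlation). H19 had -6.60 ± 0.67 in WT and -4.96 ± 0.62 in KO, the growth factor gene Igf2 -6.08 ± 0.71 and -5.77 ± 0.70, and Mest -7.70 ± 0.87 and -7.66 ± 0.87, all falls. Of 40 cytoplasmic ribosomal protein genes 32 fell in WT and 18 in KO (35 and 19 adjusted over the list alone). Their medians were -1.75 and -1.29, with adjusted p = 1.90e-07 and 1.64e-05 (adjusted p = 0.504 and 0.602 with an estimated correlation). Integrated stress response and one-carbon genes fell too, 10 of 17 in WT and 11 in KO with 1 rise in KO (10 and 12 adjusted over the list alone). Their medians were -2.04 and -2.30, with adjusted p = 0.00184 and 8.27e-04 (adjusted p = 0.410 and 0.422 with an estimated correlation). The serine synthesis enzyme Phgdh had -6.35 ± 0.62 in WT.

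Interferon response genes rose in adults, 15 of 20 in WT and 13 in KO (18 in WT and 18 in KO adjusted over the list alone), with medians of 2.07 and 2.21 and adjusted p = 3.53e-06 and 3.08e-05 (adjusted p = 0.410 and 0.422 with an estimated correlation). Irf7 rose by 4.96 ± 0.63 in WT and 2.91 ± 0.58 in KO. Circadian clock genes rose, 7 of 16 in WT and 8 in KO (9 in each adjusted over the list alone), with 1 fall in WT, medians of 1.54 and 2.12 and adjusted p = 0.00337 and 0.00629 (adjusted p = 0.410 and 0.425 with an estimated correlation). Dbp rose by 5.53 ± 0.72 in WT and 5.89 ± 0.73 in KO. Cardiac transcription factor genes split, 8 of 25 rising and 8 falling in each genotype (8 and 8 in WT and 9 and 9 in KO adjusted over the list alone; list adjusted p = 0.515 and 0.507). Hand1, which is needed for early heart growth, was at least 201-fold lower in WT adults and at least 212-fold lower in KO adults, while Srf rose by 3.25 ± 0.48 and 3.76 ± 0.49. Of 16 hypertrophy and load genes 3 rose and 7 fell in WT, and 3 and 6 in KO (3 and 7 in each genotype adjusted over the list alone), with 9.16 ± 0.82 for Xirp2 and -4.01 ± 0.57 for the endothelin gene Edn1 in WT (list adjusted p = 0.189 and 0.386). Of 17 p53 and apoptosis genes 1 rose and 5 fell in each genotype (2 and 5 in WT and 1 and 5 in KO adjusted over the list alone; list adjusted p = 0.515 and 0.452). Immediate early and heat shock genes had 1 rise and 6 falls in WT, and 0 rises and 7 falls in KO, the same numbers adjusted over the list alone (list adjusted p = 0.248 in WT and 0.0397 in KO, and adjusted p = 0.602 with an estimated correlation in KO).

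Markers of other cell types also moved with age. Of 14 erythroid markers 13 fell and 1 rose in each genotype, over all genes and adjusted over the list alone. The medians were -9.04 (-7.84 with genes at 0 in a group set to their bound) in WT and -9.36 (-8.03 with genes at 0 in a group set to their bound) in KO, with adjusted p = 1.92e-06 and 1.26e-06 (adjusted p = 0.410 and 0.409 with an estimated correlation). Of 14 atrial markers 2 rose and 8 fell in each genotype (3 and 8 in WT and 2 and 8 in KO adjusted over the list alone), with medians of -4.80 in WT and -4.28 (-3.91 with genes at 0 in a group set to their bound) in KO and adjusted p = 0.0150 and 0.0306 (adjusted p = 0.435 and 0.515 with an estimated correlation). Dkk3 fell with -7.38 ± 0.74 in WT, and 8 of the 14 atrial markers also belong to another list, such as Nppa to the fetal cardiac genes. Epicardial markers fell, 7 of 14 in each genotype against 1 rise (8 and 1 adjusted over the list alone), with medians of -2.33 and -2.22 and adjusted p = 0.0153 and 0.00629 (adjusted p = 0.435 and 0.425 with an estimated correlation). Krt18 had -5.19 ± 0.59 in WT. Of 10 skeletal muscle markers 8 fell in WT and 6 in KO (9 and 6 adjusted over the list alone). The medians were -5.12 (-4.80 with genes at 0 in a group set to their bound) in WT and -4.36 (-2.72 with genes at 0 in a group set to their bound) in KO, with adjusted p = 3.74e-04 and 0.00578 (adjusted p = 0.410 and 0.515 with an estimated correlation). Among them, Tnnt1 went from 323 ± 163 to 10.1 ± 1.34 CPM in WT, a troponin gene that fetal heart also expresses. Extracellular matrix genes fell in WT, 13 of 26 against 1 rise, over all genes and adjusted over the list alone, with a median of -2.17 (adjusted p = 0.0153, and adjusted p = 0.627 with an estimated correlation), and Eln had -6.22 ± 0.92. In KO 5 of these rose and 7 fell (5 and 10 adjusted over the list alone; list adjusted p = 0.345). Endothelial markers passed as a list in KO (median 0.95, adjusted p = 0.0441, and adjusted p = 0.602 with an estimated correlation) and had adjusted p = 0.0865 in WT, with Ly6c1 rising by 7.21 ± 0.65 in WT and 7.48 ± 0.66 in KO. In that list 4 rose and 1 fell in WT and 6 rose in KO, and adjusted over the list alone 4 and 6 rose. Among members that went against their lists, named after their values were seen, were the calcium channel gene Cacna1g (2.63 in WT) among fetal cardiac genes, the retinal dehydrogenase gene Aldh1a1 (2.40) among epicardial markers and the collagen gene Col15a1 (3.44) among matrix genes.

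The remaining lists did not pass with age in either genotype. Fibroblast markers had 3 rises and 3 falls in WT and 4 and 2 in KO (list adjusted p = 0.409 and 0.168), with Pi16 rising by 3.19 ± 0.47 and Vim at -2.37 ± 0.57 in WT. Smooth muscle and pericyte markers had 5 rises and 3 falls in each genotype (list adjusted p = 0.228 and 0.131), with Cnn1 at -9.91 ± 1.02 and Abcc9 at 3.92 ± 0.53 in WT. Macrophage and leukocyte markers had 7 rises and 2 falls in WT and 6 and 1 in KO (list adjusted p = 0.175 and 0.163), with Mrc1 at 3.15 ± 0.59 in WT. Neural crest, neuron and Schwann cell markers had 6 falls in WT, and 1 rise and 6 falls in KO (list adjusted p = 0.0531 and 0.0848). Conduction system markers had 3 rises and 6 falls in WT and 2 and 6 in KO (list adjusted p = 0.248 and 0.209), with the connexin Gja5, also a member of the calcium and ion channel list, at -5.15 ± 0.66 in WT. Adipocyte markers had 2 rises in each genotype (list adjusted p = 0.225 and 0.422), liver and lung markers 1 fall in WT and 1 rise and 1 fall in KO (list adjusted p = 0.764 and 0.498), and sex-linked genes 2 rises and 1 fall in each genotype (list adjusted p = 0.248 and 0.422). For the sex-linked genes age cannot be told apart from the differing sex of the samples. Adjusted over the list alone, the numbers in WT and KO were 3 rises and 3 falls against 4 and 2 for fibroblasts, 5 and 3 against 7 and 3 for smooth muscle, 7 and 2 against 6 and 1 for leukocytes, and 0 and 6 against 1 and 6 for the neural list. They were 3 and 6 against 3 and 6 for conduction, 2 and 0 against 2 and 1 for adipocytes, 0 and 1 against 0 and 1 for liver and lung, and 3 and 1 against 3 and 1 for sex-linked genes. With fry, which tests a list without comparing it with other genes, 22 of 32 lists passed in each genotype, while with an estimated correlation in camera 0 passed in either.

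In KO, the same comparison of ages was made. Among the large rises were those of Mylk4 (at least 1817-fold), the pacemaker channel gene Hcn2 (at least 668-fold), the sodium channel subunit Scn4b (at least 544-fold), Vtn (at least 482-fold), Pm20d2 (at least 424-fold), the macrophage receptor gene Cd163 (at least 399-fold), and the pseudogenes Rps6-ps4 and Rpl10-ps1. Hbb-y was at least 257152-fold lower, Hba-x at least 28422-fold, Hbb-bh1 at least 1291-fold and Igf2bp1, an embryonic RNA-binding protein gene, at least 1535-fold. Tnni1 fell from 2124 ± 1331 CPM to 2 counts, and Myl7 with a log2 fold change of -13.37 ± 1.61. The steroid enzyme gene Hsd3b6 and the secretory granule gene Chga fell as well, but their e13.5 libraries differed, with 417 and 30.7 CPM for Hsd3b6 and 0.813 and 135 CPM for Chga. Across the 16623 genes the changes with age in WT and KO, which share no library, correlated with r = 0.920 and rho = 0.942, and the total least squares slope of KO on WT was 1.06. Of the 7773 genes changed in either genotype, 7736 had the same sign in both, and 5573 were changed in both.

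**Figure D4:**
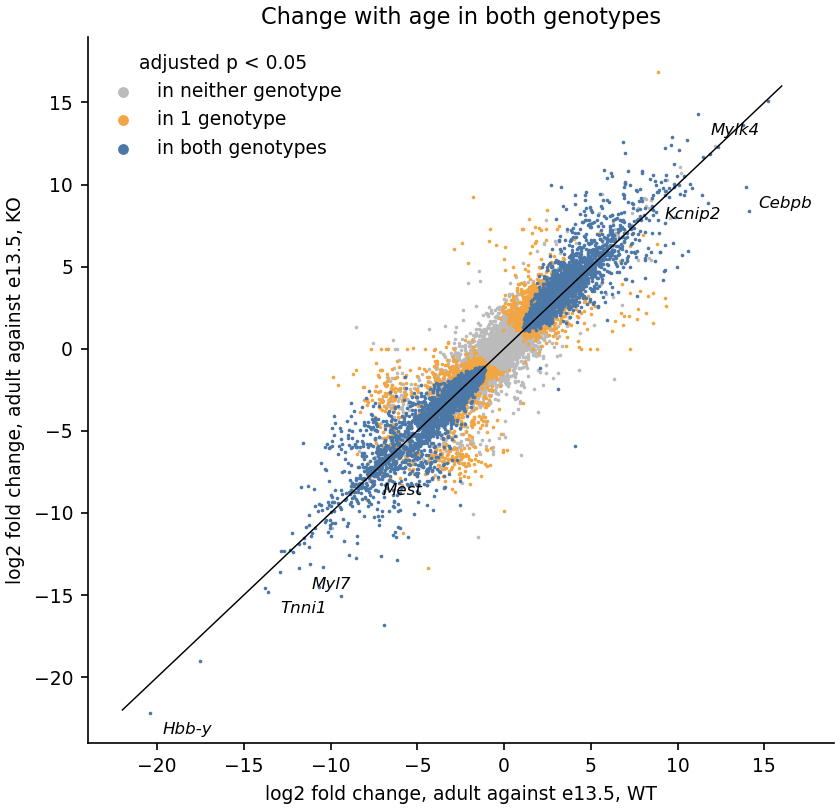
Log2 fold change of each of the 16623 genes, adult against e13.5, in WT (horizontal axis) and KO (vertical axis), colored by whether the adjusted p was under 0.05 in both genotypes, in 1 or in neither; the line marks equal change. Most genes lie near the line, with r = 0.920, from Hbb-y at the lower left to Mylk4 at the upper right.

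The interaction of genotype and age asked which genes changed differently with age in KO and WT. With edgeR 0 genes passed, 265 had an unadjusted p under 0.05, and the smallest adjusted p was 0.273. DESeq2 called 7, and edgeR without a filter 30 (16 higher and 14 lower). Among the genes of smallest p were Pttg1 (-6.29 ± 0.88, adjusted p = 0.273), with 47.2 ± 27.9 CPM in WT and 125 ± 72.8 CPM in KO at e13.5, and Mocs1 (4.44 ± 0.65, adjusted p = 0.273). Further values were -5.01 ± 0.97 for Angptl7, -4.37 ± 0.86 for Tmem100, 3.98 ± 0.81 for Pagr1a, 2.88 ± 0.65 for the nonmuscle myosin gene Myh14, -2.55 ± 0.60 for Fkbp5, 3.23 ± 0.76 for Efnb3, 3.41 ± 0.91 for the clock gene Arntl and 2.74 ± 0.73 for Angptl4, none of which passed. Atp2a2 had 0.12 ± 0.73, Myh6 0.83 ± 0.80 and Nppa 0.23 ± 1.33. Of the 32 lists, 5 passed with the preset correlation, each with adjusted p = 0.826 with an estimated correlation and 0 with fry. Extracellular matrix genes, with 23 of 26 differences positive, had a median of 1.35 (adjusted p = 5.69e-05). Ribosomal protein genes had 0.52 (adjusted p = 0.0232), skeletal muscle markers 0.63 (adjusted p = 0.0188), cell cycle genes -0.28 (adjusted p = 0.00333), and immediate early and heat shock genes -0.79 (adjusted p = 0.00347). The number of genes was 5 without WT e13.5 replicate 1 and 2 without KO e13.5 replicate 2, and the number of lists 3 without WT adult replicate 1, 12 without KO e13.5 replicate 1 and 8 without KO e13.5 replicate 2. Of the 5 lists, 2 passed without WT adult replicate 1, WT e13.5 replicate 2 or KO e13.5 replicate 2, 3 without WT e13.5 replicate 1, KO e13.5 replicate 1 or either KO adult library, and 4 without WT adult replicate 2.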

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

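The tests of near-identical copies and of other splits of the libraries were written down before their results were seen, while those of neighbouring genes, of chromosomes, of the e13.5 libraries and of the adult lists were chosen only after the result was seen.

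The change with age differed between KO and WT in 5 lists by the interaction test with the preset correlation, and in 0 lists with an estimated correlation (adjusted p = 0.826 for each of the 5). The medians of the difference, KO minus WT on the log2 scale, were 1.35 for extracellular matrix genes, 0.63 for skeletal muscle markers, 0.52 for cytoplasmic ribosomal proteins, -0.28 for cell cycle genes and -0.79 for immediate early and heat shock genes.

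A set of genes such as Gm10020 and Gvin1 was counted in one genotype and nearly absent from the other at both ages. The genotype split gave 17 genes with additive terms against at most 2 in the other splits. The 1 of 34 that called as many was the genotype split itself, so no smaller share was possible. Each other split mixes the genotypes, which can widen its spread and lower its calls, so chance is not excluded. Of the 20 genes changed on average, 75% had a near-identical transcript elsewhere, against 6.25% of genes of like level (Fisher's exact p = 3.49e-13). This was largely set in advance, since 10 of the 20 are pseudogenes, which are copies of other genes, and genes were matched on level alone. Among those that are no pseudogenes the share was 50%, against 18 of 200 genes of like level (Fisher's exact p = 0.00179). The genes are not independent, as some, such as Rpl3 and Rpl3-ps1, are copies of each other. Reads shared between copies may account for part of the pattern. A single stretch of genome around the deleted gene is argued against as the source of all 20 genes, since they lay on 12 chromosomes with at most 15% on any 1. It could still account for some of them, because LncSync was not located and reads of near-identical copies can come from another place. A strain variant against the reference, in stretches that differ between the lines, stays a candidate explanation for 1 group on chromosome 7 (Gvin1, Trim12a, Trim5 and Gm5900), which gave all 6 pairs within 2 Mb among 27 genes, the 20 and 7 more at 0 in one genotype (a share of 0.0013 of 10000 draws had as many), whereas the 20 alone held 1 pair (a share of 0.399). An effect of the genotype itself stays open and untested, because any difference in background between the lines would go with the genotype.

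At e13.5 the libraries numbered 1 differed from those numbered 2 alike in both genotypes. A difference in ribosomal RNA is argued against, since its share fell by 6.68 percentage points from replicate 2 to replicate 1 in KO and was 4.46 points higher in WT. Transcript length bias may account for part of it, with a Spearman rho across genes between length and the difference of -0.361 in KO and -0.521 in WT, both beyond the size of 0.3 set for the test. A larger atrial share cannot be told apart. The atrial list lay above the ventricular one by 0.263 in KO and 1.62 in WT, but the ventricular list was not below the median of all genes in KO. Haemoglobin genes took a larger part of the counts in replicate 1, 4.65% against 2.89% in WT and 15.5% against 3.19% in KO. Erythroid markers also lay higher there, by a median of 1.10 in WT and 2.67 in KO (camera adjusted p = 0.00130, and 0.621 with an estimated correlation). How far blood cells account for the other differences cannot be told. The test set for this was the gap between the atrial and ventricular lists, which was 1.13 standard errors over genes in KO and 2.65 in WT. It cannot decide the question, because such a gap can occur with or without more blood cells. Apart from these shares of cells, no biological explanation was tested, because the labels give none for the replicate numbers.

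In adult KO libraries extracellular matrix and leukocyte genes lay higher, and epicardial and immediate early genes lower, with the preset correlation alone (adjusted p = 0.814 for matrix genes and 0.683 for the other 3 lists with an estimated correlation). A lower share of cardiomyocytes cannot be told apart, because 15 of 15 fibroblast, 14 of 17 endothelial and 18 of 19 leukocyte markers had positive fold changes against 1 of 14 epicardial ones, and leukocyte and epicardial markers lay 6.30 standard errors apart over genes, but between libraries the gap differed by 1.11 with a standard error of 0.352, from 2 libraries per group, too few for an exact test to pass. Single libraries carried the leukocyte and epicardial lists, with leukocyte levels of 0.48 and 0.11 in WT and 0.98 and 0.24 in KO replicates 1 and 2, and epicardial levels of -0.77 and -0.55 in WT and -0.90 and -2.02 in KO (log2, centred over all libraries), while matrix genes lay at -0.55 and -1.31 in WT and 0.04 and -0.89 in KO. Immediate early and heat shock genes lay at 0.27 and -0.396 in WT and -0.996 and -0.487 in KO. Most of their difference thus came from the libraries numbered 1. Another hour of collection may account for part of it, since clock genes of opposite phase moved apart by 1.35 on the log2 scale, with medians of 0.37 and -0.99 (Mann-Whitney exact p = 0.0400). That test takes 5 and 10 genes as units, which are not independent and come from 2 libraries per group. The KO libraries differed, with 134 and 40.7 CPM for Dbp and 5.34 and 14.9 CPM for Arntl. Nr1d1 is not among the 5 genes with the median of 0.37, yet it rose as Arntl did. It had 49.3 and 34.2 CPM in WT replicates 1 and 2 and 195 and 94.98 CPM in KO. Per3, Tef and Hlf, also outside those 5, fell. Over the whole clock list 5 fold changes were positive and 11 negative. Not every gene outside those 5 thus moved in the direction of its median. These values bear on clock genes alone, and a link to the other lists was not tested. An effect of the genotype on these lists stays open and untested.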

How the results depend on the processing

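The tests chosen only after the data were seen were the replicate block at e13.5 alone, the fits without ribosomal RNA, mitochondrial and haemoglobin genes, and the additive model. Of the fold changes followed through the alternatives none reversed, but the balance of higher and lower genes did. It turned over at e13.5 without WT e13.5 replicate 1 (10 and 25) and without a filter (32 and 55), in adults without a filter (29 and 35), with DESeq2 (23 and 31) and with the 4 libraries alone (0 and 2), and for the average without a filter (46 and 54), with DESeq2 (28 and 31) and without WT e13.5 replicate 1 (17 and 18). For age it turned over in each genotype when any 1 of its 4 libraries was left out (such as 1734 and 1256 without WT adult replicate 1), and in KO without a filter (3899 and 3624) and with its 4 libraries alone (3388 and 3369). With the replicate number as a block at e13.5 alone it turned over in adults (10 and 12), for the average (16 and 17) and for age in KO (5214 and 4770). The cause of the changes was not tested except where fewer libraries or more genes entered a fit. Over all alternatives the named genes kept their direction and their side of the threshold in 268 of their tests for KO against WT at e13.5, with 17 losing and 9 gaining the threshold, and in adults in 178, with 30 and 44. For age the numbers were 1757 and 40 lost in WT and 1770 and 40 lost in KO.

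Without a filter on low counts, the changed genes were 87 in place of 12 at e13.5, 64 in place of 8 in adults, 30 in place of 0 for the interaction and 100 in place of 20 for the average, lists were 2 in place of 4 at e13.5 and 3 in place of 5 for the interaction, and the correlations were 0.0676 between the KO-WT changes and 0.743 between the age changes. The stricter filter gave 8 lists at e13.5 and correlations of 0.325 and 0.958. Median-of-ratios scaling gave 13 genes in adults. With only the 4 libraries of the comparison there were 5 genes at e13.5 and 2 in adults. The DESeq2 Wald test gave 30 genes at e13.5, 54 in adults, 7 for the interaction and 59 for the average, and 11 lists at e13.5. Camera with an estimated correlation gave 0 lists in each of the 5 comparisons, and fry 0 for KO against WT at e13.5, in adults and for the interaction. Median-of-ratios scaling shifted the median of all genes by 0.12 at e13.5, -0.10 for age in KO and -0.13 for the interaction, and upper quartile scaling by -0.13 for age in WT and -0.19 for age in KO.

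Leaving out 1 library at a time, with the lone library assumed to vary like the others, gave 8 to 35 genes at e13.5, 0 to 6 in adults, 2990 to 6965 for age in WT, 3710 to 6530 for age in KO, 0 to 5 for the interaction and 11 to 35 for the average. Lists ranged from 6 to 10 at e13.5, 5 to 11 in adults, 15 to 17 and 16 to 19 for age in WT and KO, and 3 to 12 for the interaction. The correlation of the KO-WT changes ranged from 0.105 to 0.169 and that of the age changes from 0.851 to 0.887.

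The replicate numbers are shared by all groups, but the labels do not say what they mark. The deviations of replicate 1 from replicate 2 correlated across genes with 0.552 between WT and KO at e13.5, 0.307 between WT and KO adults, and -0.0321 to 0.164 between the ages. A replicate block over all libraries gave 12 genes at e13.5, 9 in adults, 7614 and 8081 for age in WT and KO, 0 for the interaction and 24 for the average, and 6, 10, 17, 18 and 7 lists in the first 5 of these comparisons. A replicate block at e13.5 alone gave 22 genes in adults (10 higher and 12 lower), 1 for the interaction, 33 for the average (16 higher and 17 lower) and 10 lists at e13.5, and changed no other count by more than 1.5 times, with 5214 higher and 4770 lower for age in KO. Without ribosomal RNA, mitochondrial and haemoglobin genes there were 12 genes at e13.5, 12 in adults and 26 for the average. The additive model gave 17 genes. Depth set a floor of 0.103 to 0.207 CPM per library.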

Other observations

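All values in this part were chosen only after the data were seen. At e13.5, 3403 genes differed between the libraries numbered 1 and those numbered 2 across both genotypes, 1280 higher and 2123 lower in replicate 1. The integrin gene Itgb1, a receptor for matrix proteins, lay at 82.5 and 464 CPM in WT replicates 1 and 2 and at 56.1 and 490.0 CPM in KO. Hspa4, a heat shock protein gene, lay at 23.2 and 142 CPM in WT and 15.6 and 115 CPM in KO, and the histone deacetylase gene Hdac2 at 10.3 and 68.6 CPM in WT and 9.06 and 50.2 CPM in KO. Oxidative phosphorylation genes had a median log2 difference of 1.22 between replicate 1 and 2 (adjusted p = 0.460 with an estimated correlation), fatty acid oxidation genes 1.02 (adjusted p = 0.396 with an estimated correlation) and extracellular matrix genes -1.81 (adjusted p = 0.621 with an estimated correlation). In 4 groups of genes of rising transcript length the medians were 0.71, 0.38, -0.28 and -1.08 in WT, and 0.60, 0.29, -0.33 and -0.49 in KO.

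In all, 12 genes had 0 counts in all 4 libraries of one genotype and counts in all 4 of the other, against 0 genes in each of the 4 other splits tried. The 7 at 0 in KO were C430049B03Rik, Gvin1, Gm16867, Trim5, Gm26760, Hist1h4m and Gm43609, and the 5 at 0 in WT were Gm10020, Mrpl48-ps, Gm12663, Gm5900 and Gm18860. Trim5, of the same family as Trim12a, lay at 0.587 CPM in WT at e13.5 and 1.47 CPM in WT adults. Across genes, the KO-WT fold change correlated with transcript length with a Spearman rho of -0.264 at e13.5 and -0.171 in adults, and with GC content 0.0109 and 0.180. Between replicates 1 and 2 of KO adults the rho with GC content was 0.441, against 0.0468 in WT adults.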
